A study of Salmo salar with 26 samples.

How the data were processed

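RNA was sequenced from the lenses of 26 Atlantic salmon (Salmo salar), per the labels as poly(A) selected libraries read from 1 end over 50 bases. The fish were diploid (2N) or triploid (3N) and had lenses without (-) or with (+) cataract, which gave 4 groups of 6 (2N-), 6 (2N+), 6 (3N-) and 8 (3N+) fish. Each library came from a separate fish, and the labels give each fish a body weight and a length. Libraries that share a replicate number across groups were checked for pairing. The correlations of residuals within same-numbered sets exceeded 0.1 in 11 of 24 pairs, and 3 of 26 libraries were closest to a library of their own number, so the numbers were read as numbers and not as pairs.

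The authors deposited 1 table of RPKM values, which are read counts scaled by contig length and library size, for 26681 unigenes, which are transcript contigs assembled without a genome. The assembler, the aligner and any genome build are not given in the sources used here. The table also carries each unigene's ontology terms and best protein hit, and these hits were the source of every gene name printed; 13784 unigenes had a hit. A name therefore says which known protein a contig most resembles, several contigs can carry 1 name, and a contig may be a fragment or may collect reads from near-identical gene copies of the salmon genome. A dash in the table was read as 0. The deposited RPKM values allowed whole read counts to be recovered for 100% of unigenes within a tolerance of 0.01 reads, and for 3975 of 3983 unigenes in a simulated table. The recovered totals, which are the denominators of the RPKM scaling, ran from 9.76 to 11.95 M reads per library, with a median of 14 reads per unigene and library, and this number of reads limits the precision for unigenes of low abundance.

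A count model had been planned before the data were examined, as had the contrasts, the gene lists, the rule for naming genes, the filter and most alternatives. Because the values were RPKM, the main test was limma's empirical Bayes test (trend and robust) on log2 of the scaled RPKM plus 0.5. Scaling factors came from the trimmed mean of M values (TMM, trims of 0.3 and 0.05) on the recovered reads, programmed for this purpose. Unigenes were tested if at least 6 libraries exceeded 10 reads at the median library size and the reads totalled at least 15, which left 19532. One model with 4 group means gave the 4 pairwise contrasts, the average cataract contrast over both ploidies, the average ploidy contrast over both cataract states, and the interaction. A further model added log2 body weight within groups. P-values were two-sided and adjusted by Benjamini-Hochberg at 0.05 over all unigenes tested. On simulated data with the diploid cataract groups the test called 43.3% of unigenes changed 2-fold and 91.8% of those changed 4-fold, and 4 of 19181 unchanged ones. The simulation drew each unigene independently and so lacked the variation that unigenes share across the real libraries. Its rate of false calls therefore need not hold for the real data. Log2 changes refer to the scaled values, whereas group levels are means of RPKM as deposited with their SD, so the ratio of printed means can differ from the printed change. Counts of lenses above or below all lenses of another group also use RPKM as deposited. The scaling factors averaged 0.944 in 2N- and 1.163 in 2N+, so these counts could differ on the scaled values.

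Gene lists (27) were built from gene symbols and words of the protein descriptions: crystallins, lens fibre structure, lens epithelium regulators, heat shock proteins and chaperones, endoplasmic reticulum stress, antioxidants and glutathione, extracellular matrix, epithelial-mesenchymal transition and TGF-beta, calcium and calpains, ion and water transport, histidine and amino acid transport, glycolysis and polyols, oxidative phosphorylation, sterol synthesis, fatty acids and lipids, cell cycle, p53 and DNA damage, proteasome and ubiquitin, autophagy and lysosome, cytosolic ribosomal proteins, and immune and inflammatory genes, with markers of leukocytes, erythrocytes, retina, pigment cells, keratinised surface epithelium, and muscle and vessels. Of these, 26 had tested members. Membership by wording placed a few unrelated proteins in lists, such as RhoB among the retina markers, and the wording for crystallins missed an alpha A crystallin. Lists were tested with camera (preset correlation 0.01) on log2 RPKM, adjusted over lists within a contrast, with camera on an estimated correlation and fry beside it. Ontology terms were tested with Fisher's exact test against the 7567 tested unigenes that carry a term. Single measures were compared by two-sided exact permutation tests, adjusted over the 4 pairwise comparisons of each measure.

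Genes were named by rule: per contrast, among named genes with an adjusted p below 0.05 and a mean log2 CPM of at least 1, the 12 highest and 12 lowest log2 changes; where fewer than 5 genes passed, the 5 smallest p; up to 4 passing members of each list; and the 3 most abundant crystallin, lens fibre and lens epithelium unigenes. Alternatives covered relative log expression and upper quartile factors, TMM without crystallins, RPKM as deposited, filters, pseudocounts of 0.1 and 1, voom with and without sample quality weights on the recovered reads, body weight or the first principal component or both as covariates, the 2 compared groups alone, a replicate block, libraries rich or poor in epithelial transcripts alone, and leaving out each fish. Group labels were reassigned at random in 100 splits of the libraries for each contrast. Calculations used R 4.3.3 with limma 3.58.1 and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The study's raw reads were not analysed here.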

Results

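The lens transcriptome was measured in 26 Atlantic salmon, 6 diploids without cataract (2N-), 6 diploids with cataract (2N+), 6 triploids without cataract (3N-) and 8 triploids with cataract (3N+). Each lens library came from its own fish. The libraries held 9.76 to 11.95 M counted reads. Their mean was 10.82 ± 0.37 M (SD, n = 6) in 2N-, 11.55 ± 0.31 M (n = 6) in 2N+, 10.98 ± 0.19 M (n = 6) in 3N- and 11.04 ± 0.67 M (n = 8) in 3N+. The diploid difference in counted reads was 0.729 M (exact permutation p = 0.00649, adjusted p = 0.026 over 4 comparisons). Crystallins, the structural proteins of the lens, took 39.2 ± 2.69% (SD, n = 26) of the reads, and the 10 most abundant unigenes of each library took 31.3 to 39.4%.

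Body weight differed between the groups. The 2N- fish weighed 257 ± 80.6 g (SD, n = 6), the 2N+ fish 596 ± 158 g (n = 6), the 3N- fish 510 ± 162 g (n = 6) and the 3N+ fish 606 ± 221 g (n = 8). On the log2 scale the difference was 1.26 between 2N+ and 2N- (exact permutation p = 0.00216, adjusted p = 0.00866), with each of the 6 cataract fish heavier than each of the 6 without. The 3N- fish were heavier than the 2N- fish by 253.3 g (exact permutation p = 0.0108, adjusted p = 0.0216). The triploid cataract groups differed by 0.21 (exact permutation p = 0.505, adjusted p = 0.674) and the ploidies with cataract by -0.04 (exact permutation p = 0.886), a difference that in grams was 9.79. The crystallin share of reads was 41.1 ± 2.37% (SD, n = 6) in 2N-, 37.2 ± 3.17% in 2N+, 39.9 ± 2.17% in 3N- and 38.8 ± 2.02% (n = 8) in 3N+. The diploid difference of -3.89 percentage points did not pass after adjustment (exact permutation p = 0.0455, adjusted p = 0.182), and the triploid difference was -1.13 (exact permutation p = 0.317, adjusted p = 0.351). The ploidy differences in the crystallin share were -1.23 without cataract (exact permutation p = 0.351, adjusted p = 0.351) and 1.53 with cataract (exact permutation p = 0.283, adjusted p = 0.351).

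**Figure D1:**
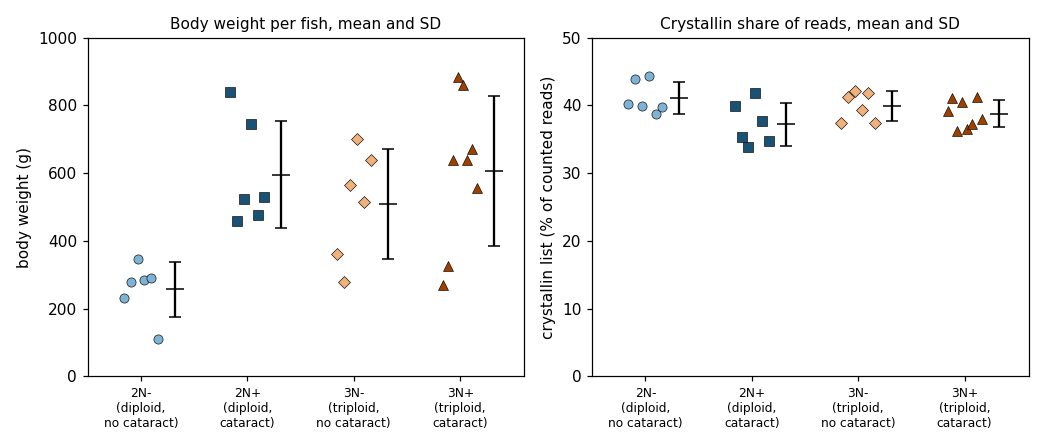
Body weight in grams and the percent of reads in crystallins for each fish (points) by group, with the group mean and SD (bars). The 2N+ fish averaged 596 g and the 2N- fish 257 g, while the crystallin shares of the groups overlapped.

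The first principal component held 35.3% of the variance and followed transcripts of the lens epithelium, the cell layer on the front of the lens. Connexin 43, the gap junction protein of that layer, ran from 0.42 to 109.5 RPKM across the 26 lenses. It averaged 44.7 ± 33.8 RPKM (SD, n = 6) in 2N-, 52.2 ± 48.2 (n = 6) in 2N+, 26.8 ± 28.5 (n = 6) in 3N- and 22.5 ± 29.4 (n = 8) in 3N+. Both kinds of library, rich (at least 23.7 RPKM) and poor (at most 7.89 RPKM) in connexin 43, occurred in each group, with 4 rich and 2 poor in 2N-, 4 and 2 in 2N+, 3 and 3 in 3N-, and 3 and 5 in 3N+. Component 1 did not differ in the 4 pairwise comparisons (smallest exact permutation p = 0.256, adjusted p = 0.967). Component 2 held 10.1% of the variance and was higher with cataract by 32.9 in diploids (exact permutation p = 0.00216, adjusted p = 0.00866) and by 33.8 in triploids (exact permutation p = 0.00699, adjusted p = 0.00932). It was also higher by 7.13 in 3N- than in 2N- (exact permutation p = 0.00649, adjusted p = 0.00932).

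**Figure D2:**
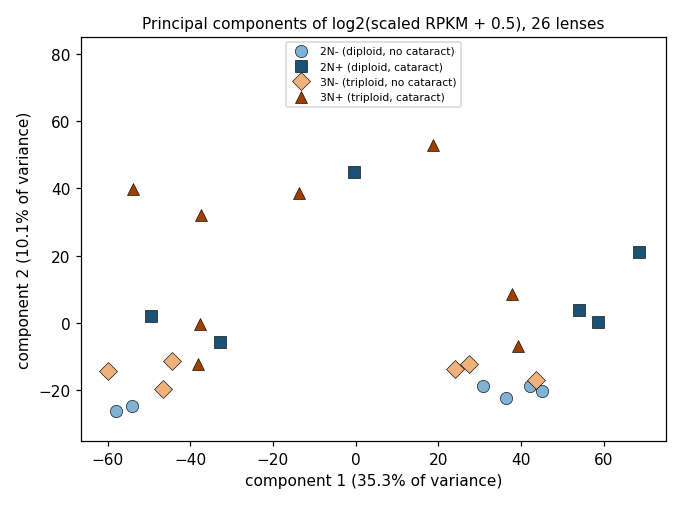
Libraries on the first (35.3% of variance) and second (10.1%) principal component, 1 point per fish in the colour of its group. All 4 groups spread along component 1, and 13 of the 14 cataract libraries lie above the highest library without cataract (-11.4) on component 2.

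The comparison of 2N+ with 2N- asked which lens transcripts differ with cataract in diploid fish. Adenosine deaminase (Unigene4383), which converts adenosine to inosine, was 60.5 ± 8.14 RPKM (SD, n = 6) without cataract and 21.9 ± 19.2 RPKM (n = 6) with cataract. A DEPTOR-like transcript (Unigene4123), named for a protein that binds and inhibits mTOR, was 90.6 ± 12.2 RPKM without and 36.8 ± 26.1 RPKM with cataract. A homer homolog 2-like transcript (CL3023.Contig2), of a family of synaptic scaffold proteins, was 41.1 ± 8.83 RPKM without and 13.5 ± 8.14 RPKM with cataract. In the other direction a Rab-32-like small GTPase (Unigene10053), of a family that directs vesicle traffic, was 1.27 ± 0.51 RPKM without and 7.65 ± 3.32 RPKM with cataract. The Maf-like transcription factor (Unigene8519), of a family that drives crystallin genes in fibre cells, was 10.2 ± 1.79 RPKM without and 19.2 ± 3.09 RPKM with cataract. All 5 passed the limma test.

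On the scaled values, adenosine deaminase fell by 2.06 ± 0.39 (log2, SE; adjusted p = 0.00871) and the DEPTOR-like transcript by 1.87 ± 0.36 (adjusted p = 0.0108). On RPKM as deposited, each lay below all lenses without cataract in 5 of 6 cataract lenses. The homer-like transcript fell by 2.09 ± 0.41 (adjusted p = 0.011), in 6 of 6. The Rab-32-like transcript rose by 1.88 ± 0.31 (adjusted p = 0.00305) and the Maf-like factor by 0.61 ± 0.15 (adjusted p = 0.0304), each above all lenses without cataract in 6 of 6. Further genes that rose were cytochrome P450 2K5 (Unigene10869, 1.67), a glutamate transporter of solute carrier family 1 (Unigene6508, 0.95), and a phocein-like MOB protein (CL2381.Contig1, 0.94). A FAM8A1-like protein (CL894.Contig1, 0.82), an acidic nuclear phosphoprotein (Unigene7697, 0.80), 40S ribosomal protein SA (CL953.Contig2, 0.78) and a beta-sarcoglycan-like protein (Unigene5783, 0.73) also rose. Type IVA tyrosine phosphatase 1 (Unigene98, 0.65), the ubiquitin ligase HUWE1 (Unigene4762, 0.62) and clathrin heavy chain (Unigene6737, 0.61), the coat protein of endocytic vesicles, rose too. Further genes that fell were the Rhes-like GTP-binding protein (Unigene6759, -1.87), an attractin-like protein (Unigene3900, -1.56), and a deltex-3-like protein (Unigene1080, -1.51). Lower levels were also found for borealin-2 (Unigene9252, -1.43), a subunit of the chromosomal passenger complex, the meiotic cohesin REC8 (Unigene6656, -1.40) and a lipocalin (Unigene4386, -1.36). A transposase (CL1639.Contig1, -1.46), a PiggyBac-derived protein (CL2685.Contig1, -1.37) and a transcript named GG24735 (Unigene9691, -1.42) fell as well. The adjusted p-values of these further genes ran from 0.00398 to 0.0491.

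Crystallins were on the lower side in diploid cataract. Of 55 tested crystallin unigenes 6 fell and 0 rose at limma's adjusted threshold, 27 fell when adjusted over the list alone, and 53 of 55 had a negative change, with a median of -0.47 (-0.20 on RPKM as deposited). Gamma-crystallin N-like (CL85.Contig1) fell by 0.97 ± 0.21 (log2, SE), from 7720 ± 751 RPKM (SD, n = 6) to 4869 ± 845 RPKM (n = 6), and lay below all lenses without cataract in 6 of 6. Gamma-crystallin B (Unigene6143) fell by 0.92, a gamma crystallin-like unigene (CL403.Contig1) by 0.79 and beta-crystallin S-1-like (CL1572.Contig1) by 1.15. The most abundant crystallins did not pass, with -0.41 for beta-B2-like (CL1905.Contig1, adjusted p = 0.251), -0.31 for gamma-M2-like (CL3805.Contig1, adjusted p = 0.421) and -0.57 for a gamma-B unigene (Unigene6863, adjusted p = 0.163). The camera test placed the crystallins lower than other genes (adjusted p = 2.72e-23), but with adjusted p = 0.889 with an estimated correlation. The lens fibre list (19 members, median -0.26, which turned to 0.03 on RPKM as deposited) was lower by camera at adjusted p = 0.000127, and at adjusted p = 0.889 with an estimated correlation. None of its members passed over all genes, 8 fell when adjusted over the list alone, and phakinin-like (CL984.Contig1), a beaded filament protein, stood at -0.78 (adjusted p = 0.0515).

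**Figure D3:**
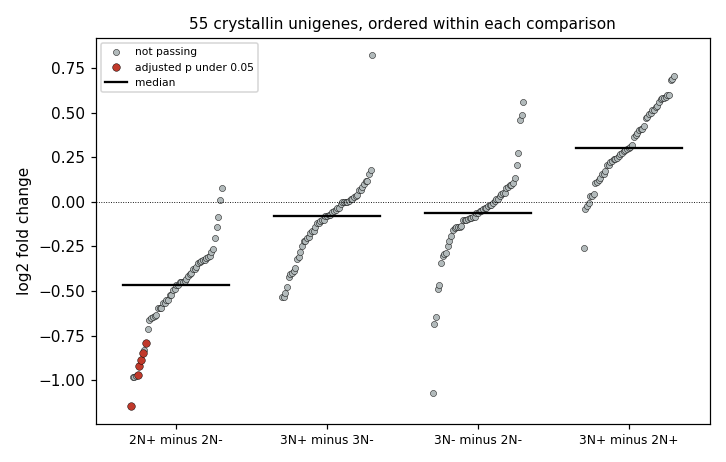
Log2 change of each of 55 crystallin unigenes in the 4 pairwise contrasts, ordered within each contrast, with bars at the median and the 6 that passed in diploid cataract in red. The diploid cataract median was -0.47 on TMM-scaled values and -0.20 on RPKM as deposited.

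No marker of retina or erythrocytes passed in diploid cataract, over all genes or over its list alone, and fry gave adjusted p = 0.53 for both lists. The 12 retina markers all had positive changes (median 0.75; camera adjusted p = 0.0483; adjusted p = 0.889 with an estimated correlation), and so did the 5 erythrocyte markers (median 2.11; camera adjusted p = 0.0319; adjusted p = 0.889 with an estimated correlation). Their share of reads was 0.101 ± 0.177% (SD, n = 6) for retina in 2N+ (0.453% in replicate 2) against 0.0101 ± 0.00885% in 2N-, and 0.0282 ± 0.0298% against 0.00317 ± 0.00204% for erythrocytes. Sterol synthesis genes (24 members, median 0.21, 0.47 on RPKM as deposited) were higher at camera adjusted p = 0.0219, and at adjusted p = 0.889 with an estimated correlation. Cytosolic ribosomal proteins (median -0.07, which turned to 0.226 on RPKM as deposited) were lower at camera adjusted p = 0.0302, and at adjusted p = 0.911 with an estimated correlation. In lists with no camera call, fibroblast growth factor receptor 2-like (CL2947.Contig1) fell by 1.18, and inducible heat shock protein 70 (Unigene8846) by 0.88, from 36.7 ± 6.07 to 24.8 ± 7.32 RPKM. The regulatory subunit of glutamate-cysteine ligase (CL709.Contig2), of the enzyme that starts glutathione synthesis, fell by 0.55. Mitochondrial methionine sulfoxide reductase (Unigene16510), which repairs oxidised methionine, fell by 1.10. Matrix metalloproteinase-14-like (CL384.Contig2) fell by 1.10, annexin A4 (CL2784.Contig3) by 0.40, the peptide transporter slc15a2-like (Unigene534) by 1.25 and cytochrome c oxidase subunit Vb (Unigene9769) by 1.31. Of the 3 most abundant lens epithelium regulators, Prox1-like (Unigene8584) stood at 0.20 (adjusted p = 0.523), a Sox-2 unigene (CL1160.Contig2) at -0.87 (adjusted p = 0.0848), and Maf-like rose.

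In total limma called 268 unigenes in diploid cataract, 54 that rose and 214 that fell. On RPKM as deposited, where the median of all unigenes shifted by 0.284, the count was 1315 with 1095 higher and 220 lower. Of the 268, 216 were among them and all 268 had the same sign. The count was 43 with body weight as a covariate and 67 in a fit of the 2 groups alone. In libraries rich in connexin 43 alone, 4 of each diploid group, it was 354. In libraries poor in connexin 43 alone, 2 of each diploid group, it was 11. It was 780 with component 1 as a covariate and 570 with voom and sample quality weights. Without 2N- replicate 1, 2 or 4 it was 162, 76 or 111, without 2N+ replicate 2, 3, 5 or 6 it was 140, 103, 110 or 140, and without 2N+ replicate 4 it was 417.

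The comparison of 3N+ with 3N- asked the same of triploid fish. Glycylpeptide N-tetradecanoyltransferase 1 (Unigene8559), which attaches myristate to proteins, was 7.43 ± 4.27 RPKM (SD, n = 6) without and 30.4 ± 13.3 RPKM (n = 8) with cataract. It rose by 1.96 ± 0.33 (log2, SE; adjusted p = 0.0128) and lay above all lenses without cataract in 8 of 8. Mitochondrial glycine cleavage system H protein (CL2430.Contig1) rose by 0.61 ± 0.11 (adjusted p = 0.0186), from 11.3 ± 1.43 to 18 ± 2.04 RPKM, in 7 of 8 lenses. A tripartite motif protein 60-like transcript (Unigene5114) fell by 1.10 ± 0.21 (adjusted p = 0.0261), from 13.1 ± 1.89 to 6.12 ± 1.55 RPKM, in 8 of 8 lenses. Chosen after their values were seen, a galanin-like transcript (Unigene12516) rose by 3.22, and a Bcl2 antagonist of cell death (Unigene5388) and a thyrotropin-releasing hormone-degrading ectoenzyme (CL2646.Contig2) fell by 1.02 and 1.35.

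Among the gene lists in triploid cataract, fatty acid and lipid genes (39 members, median -0.31, 32 negative) were lower by camera at adjusted p = 6.02e-06, and at adjusted p = 0.368 with an estimated correlation. Keratin markers of surface epithelium (6 members, median 1.95, all positive) were higher at camera adjusted p = 3.77e-05, and at adjusted p = 0.367 with an estimated correlation. Of these, 5 rose when adjusted over the list alone, among them keratin-18 (Unigene7304), at 2.71 ± 1.5 RPKM without and 45.8 ± 60.6 RPKM with cataract. Muscle and vessel markers (6 members, median 0.49) were higher at camera adjusted p = 0.00734, and at adjusted p = 0.177 with an estimated correlation. Cytosolic ribosomal proteins (median 0.08) were higher at camera adjusted p = 6.46e-05, and lens fibre genes (median -0.14) lower at camera adjusted p = 0.0356, both at adjusted p = 0.948 with an estimated correlation. The crystallins did not pass (camera adjusted p = 0.0527). Limma called 17 unigenes in triploid cataract, 9 that rose and 8 that fell, against 48 on RPKM as deposited, 179 with component 1 as a covariate, 42 with voom and sample quality weights, 10 with voom and 37 in libraries poor in connexin 43 alone. In libraries rich in connexin 43 alone the limma count was 0, and 1743 unigenes had an unadjusted p below 0.05 in the main test. Without 3N- replicate 2, 3 or 5 the count was 8, 5 or 9, and without 3N+ replicate 2, 5 or 7 it was 33, 43 or 9.

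The average of both cataract contrasts asked which transcripts differ with cataract over both ploidies. Ictacalcin (Unigene4061), a calcium-binding S100 protein, was 7.37 ± 6.72 RPKM (SD, n = 6) in 2N-, 270 ± 386 in 2N+, 7.50 ± 7.47 in 3N- and 402 ± 509 RPKM (n = 8) in 3N+. It rose by 4.13 ± 0.76 (log2, SE; adjusted p = 0.00276), and 5 of 6 diploid and 7 of 8 triploid cataract lenses exceeded all lenses without cataract of their ploidy. A galectin-3-like transcript (CL99.Contig1), of a family of carbohydrate-binding proteins, rose by 1.10 ± 0.21 (adjusted p = 0.00364), from 3.57 ± 1.06 to 9.51 ± 5.17 RPKM in diploids and from 2.99 ± 0.79 to 9.15 ± 4.68 RPKM in triploids, in 5 of 6 and 8 of 8 lenses. Adenosine deaminase (Unigene4383) fell by 1.62 ± 0.27 (adjusted p = 0.00112) and the DEPTOR-like transcript (Unigene4123) by 1.46 ± 0.25 (adjusted p = 0.00136), each below all lenses without cataract in 5 of 6 diploid and 8 of 8 triploid cataract lenses. Ceramide synthase 2-like (Unigene9745), of a family that makes sphingolipid precursors, fell by 0.98 ± 0.17 (adjusted p = 0.00129), in 5 of 6 and 7 of 8 lenses.

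**Figure D4:**
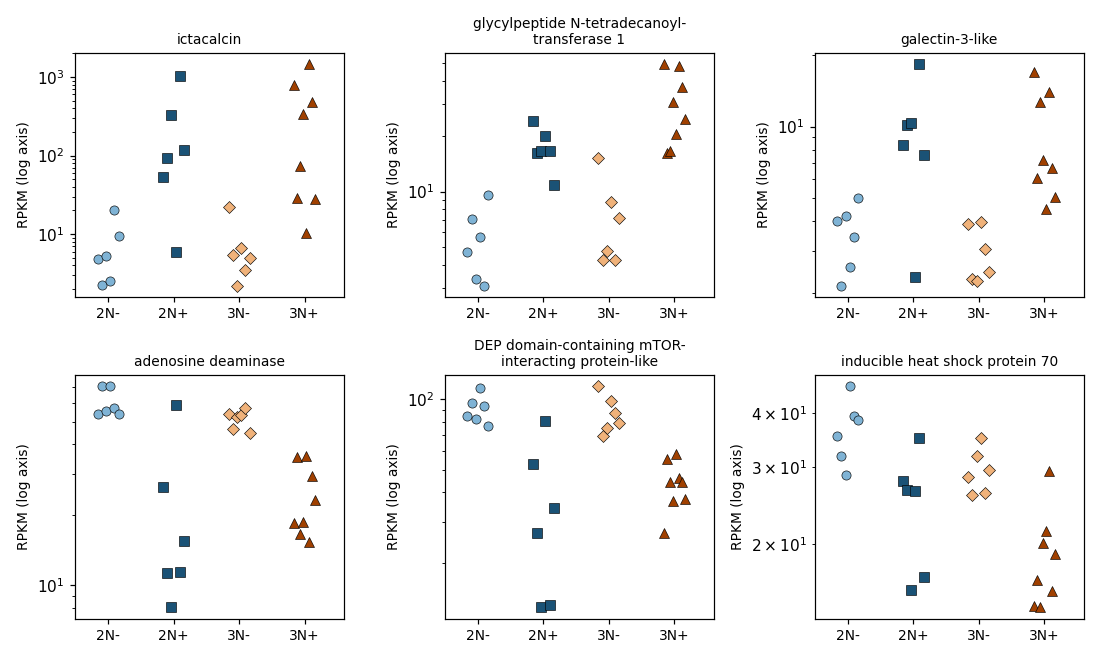
RPKM on a log axis for each fish by group in 6 panels (ictacalcin, glycylpeptide N-tetradecanoyltransferase 1, a galectin-3-like transcript, adenosine deaminase, a DEPTOR-like transcript and inducible heat shock protein 70), 1 point per fish. Ictacalcin averaged 7.37 RPKM in 2N- and 270 RPKM in 2N+, and adenosine deaminase 60.5 and 21.9 RPKM.

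Other genes that rose over both ploidies were glycylpeptide N-tetradecanoyltransferase 1 (Unigene8559, 1.65), the Rab-32-like GTPase (Unigene10053, 1.54) and the histone methyltransferase PRDM9 (CL3702.Contig2, 1.6). So did a chaperonin (Unigene6071, 1.43), zinc finger proteins 135-like (CL3702.Contig1, 1.33) and 391 (Unigene6503, 1.30), a SWI/SNF-related protein (Unigene7796, 1.01), copine-2 (Unigene13732, 1.01) and cysteinyl-tRNA synthetase (CL3670.Contig1, 0.99). A transcript named SJCHGC02514 (Unigene2714) rose by 2.61. Other genes that fell were the tripartite motif protein 60-like transcript (Unigene5114, -1.20), the homer-like (CL3023.Contig2, -1.48), Rhes-like (Unigene6759, -1.41) and attractin-like (Unigene3900, -1.15) transcripts. So were a doublecortin domain protein (Unigene3251, -1.17), a lipocalin (Unigene4386, -1.08), the transcript named GG24735 (Unigene9691, -1.07), tumor protein D54-like (Unigene9934, -0.98) and a voltage-dependent calcium channel subunit (CL913.Contig2, -0.98). Their adjusted p-values ran from 0.000101 to 0.0423. The 3 unigenes that passed and are named for heat shock protein 70, the stress-inducible chaperone, fell by 0.85 (Unigene6290), 0.80 (Unigene8846) and 0.74 (Unigene7837), out of 37 tested chaperones of which 34 did not pass. Fry found change in either direction in the heat shock list (adjusted p = 0.0084), the lens epithelium regulators and the fatty acid and lipid genes (adjusted p = 0.0274 for both), whereas camera gave adjusted p = 0.7 for the heat shock list.

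Some crystallin and lens fibre genes fell in the average over both ploidies. An average does not show a fall in each ploidy, and in triploids alone the crystallin list did not pass the camera test. Of the 55 crystallin unigenes 8 fell and 0 rose, 15 fell when adjusted over the list alone, and the median change was -0.27 (-0.10 on RPKM as deposited), with camera adjusted p = 8.46e-16 and adjusted p = 0.592 with an estimated correlation. Gamma-crystallin N-like (CL85.Contig1) fell by 0.67, with means of 6896 ± 747 RPKM in 3N- (SD, n = 6) and 5510 ± 639 RPKM in 3N+ (n = 8). Of 19 lens fibre unigenes (median -0.23, -0.07 on RPKM as deposited) 2 fell, a filensin-like (CL655.Contig4, -0.51) and a phakinin unigene (CL833.Contig2, -0.61), both named for beaded filament proteins, with camera adjusted p = 6.89e-05 and adjusted p = 0.592 with an estimated correlation. The abundant lens fiber membrane intrinsic protein-like unigenes CL1968.Contig1 and CL256.Contig3 stood at 0.04 and -0.06 and did not pass. Of 22 lens epithelium regulators 1 rose, Maf-like (Unigene8519, 0.58), and 2 fell, a Sox-2 unigene (CL858.Contig1, -0.63) and fibroblast growth factor receptor 2-like (CL2947.Contig1, -0.81), with camera adjusted p = 0.887 for the list. Among 973 ontology terms, morphogenesis of an epithelium was the only one that passed Fisher's exact test, with 4 of its 11 tested unigenes among the genes that fell against 0.161 by chance (adjusted p = 0.013), and the smallest adjusted p of the other 3 gene sets was 0.116. Its 4 members, chosen after their values were seen, were beta-crystallin S-like unigenes (Unigene7957, Unigene7954, CL619.Contig1 and CL619.Contig2), with changes of -0.68, -0.76, -0.73 and -0.65. These 4 carry the same name and may stem from near-identical copies, whereas Fisher's exact test counts them as independent, so its p-value may be too small.

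Metabolic and marker lists over both ploidies were mixed. Fatty acid and lipid genes (39 members, median -0.23, -0.07 on RPKM as deposited) were lower by camera at adjusted p = 0.00028, and at adjusted p = 0.592 with an estimated correlation. Among them 1 fell, the fatty acid elongase elovl1 (Unigene10183, -0.63). Keratin markers (median 1.40, 6 of 6 positive, 3 higher when adjusted over the list alone) were higher at camera adjusted p = 0.00225, erythrocyte markers (median 1.90) at camera adjusted p = 0.011 and muscle and vessel markers (median 0.45) at camera adjusted p = 0.0373, each at adjusted p = 0.592 with an estimated correlation. Of 59 antioxidant genes 1 rose, mitochondrial superoxide dismutase (Unigene3093, 0.28), and 1 fell, the methionine sulfoxide reductase (Unigene16510, -0.82). Of 65 oxidative phosphorylation genes 1 rose, an ATP synthase assembly factor (Unigene13605, 0.60), and 1 fell, cytochrome c oxidase subunit Vb (Unigene9769, -0.85). A collagen alpha-1(IX)-like unigene (Unigene13097) rose by 1.22 among 53 matrix genes, and 2 matrix metalloproteinase-14-like unigenes (CL384.Contig1, -0.96, and CL384.Contig2, -0.73) fell among 19 genes of the epithelial-mesenchymal transition list. Annexin A4 (CL2784.Contig3, -0.27) fell among 45 calcium genes and slc15a2-like (Unigene534, -0.80) among 10 amino acid transport genes. The median changes of lists without a camera call were 0.12 for glycolysis, 0.35 for retina markers, 0.08 for sterol synthesis and -0.16 for p53 targets. They were 0.06 for endoplasmic reticulum stress, 0.06 for autophagy, 0.07 for leukocyte markers, 0.03 for the proteasome, 0.04 for immune genes, 0.03 for the cell cycle and 0.02 for ion transport, at camera adjusted p-values from 0.0822 to 0.812. Camera made no call for the antioxidant, oxidative phosphorylation, matrix, epithelial-mesenchymal, calcium and amino acid transport lists either, at adjusted p-values from 0.394 to 0.966. Pigment cell markers had no tested member and took 0 to 0.0006% of reads.

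Over both ploidies limma called 524 unigenes, 159 that rose and 365 that fell. On RPKM as deposited, where the median of all unigenes shifted by 0.16, the count was 1432 with 1118 higher and 314 lower. Of the 524, 435 were among them. The count was 247 with body weight as a covariate, 1120 with component 1 as a covariate, 279 and 118 in libraries rich and poor in connexin 43, and 323, 343 and 344 without 2N- replicate 2, 3N- replicate 2 and 3N- replicate 3.

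**Figure D5:**
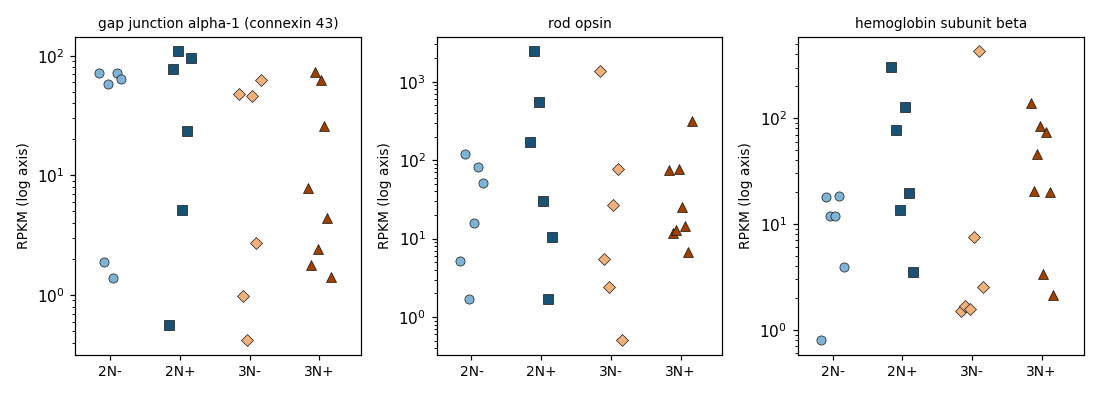
RPKM on a log axis of connexin 43 (lens epithelium), rod opsin (retina) and hemoglobin beta (erythrocytes) for each fish (points) by group. Connexin 43 ran from 0.42 to 109.5 RPKM, and rod opsin reached 2462 RPKM in a 2N+ lens.

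The cataract changes of the ploidies were compared gene by gene. Of the 268 unigenes called in diploids, 234 (87.3%) had the same sign in triploids, against 57.2% of all unigenes. Their median change was 1.03 in diploids and 0.40 in the same direction in triploids. The 268 were selected by the diploid test, which favours large diploid changes, so these 2 medians do not show a smaller change in triploids. The Pearson correlation across unigenes was 0.372, and unigenes are not independent replicates. Called in both ploidies were 2 unigenes that rose (0.0249 expected by chance), Unigene6566 and Unigene10120, and 3 that fell (0.0877 expected), the tripartite motif protein 60-like transcript (Unigene5114), Unigene9693 and Unigene2925. These counts were 2 and 1 with body weight and 12 and 76 with component 1 as a covariate. The interaction tested the difference between the ploidies itself, and 1 unigene passed in limma, the beta-sarcoglycan-like transcript (Unigene5783, -1.36 ± 0.22, log2 and SE, adjusted p = 0.0353), named for a membrane protein of the dystrophin complex. Its mean was 4.17 ± 1.10 RPKM in 2N- (SD, n = 6), 8.85 ± 2.11 in 2N+, 7.67 ± 1.57 in 3N- and 5.12 ± 1.92 RPKM in 3N+ (n = 8), with 6 of 6 diploid cataract lenses above and 6 of 8 triploid cataract lenses below all lenses without cataract of their ploidy. Neuropeptide Y (Unigene12468) stood at -1.89 (adjusted p = 0.303) and Unigene3760, Unigene16722 and Unigene11423 at 1.24, 1.17 and -0.70, none of which passed. The interaction was positive for 53 of 55 crystallins (median 0.47, 0.22 on RPKM as deposited, camera adjusted p = 3.58e-13) and for ribosomal proteins (median 0.15, which turned to -0.10 on RPKM as deposited, camera adjusted p = 7.86e-08), and negative for sterol synthesis (median -0.19, -0.42 on RPKM as deposited, camera adjusted p = 0.00938). Each had adjusted p = 0.827 with an estimated correlation. In libraries rich in connexin 43 alone the beta-sarcoglycan-like transcript did not pass and 1 other unigene did, with a positive interaction. The interaction count was 0 in libraries poor in connexin 43 alone, with body weight as a covariate, on RPKM as deposited, with voom, and in 20 of 26 fits that left out a fish, all but those without 2N- replicate 3 or 5, 3N- replicate 1 or 3N+ replicate 1, 3 or 6. In limma 1203 unigenes had an unadjusted p below 0.05.

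The comparison of 3N- with 2N- asked which transcripts differ with ploidy in lenses without cataract. A HARBI1-like nuclease (CL18.Contig2), named for a protein derived from a transposase, was 8.88 ± 4.24 RPKM (SD, n = 6) in diploids and 27.6 ± 8.19 RPKM (n = 6) in triploids. It rose by 1.63 ± 0.31 (log2, SE; adjusted p = 0.03), in 5 of 6 triploid lenses above all diploid ones. The glutamate transporters Unigene6508 (solute carrier family 1) and Unigene7465 (excitatory amino acid transporter 2-like) rose by 1.28 ± 0.24 (adjusted p = 0.03) and 1.18 ± 0.24 (adjusted p = 0.0445), each in 6 of 6 lenses, from 2.60 ± 0.62 to 7.21 ± 2.06 RPKM and from 3.84 ± 0.66 to 9.67 ± 2.42 RPKM. Cytochrome P450 2K5 (Unigene10869) rose by 2.36 ± 0.43 (adjusted p = 0.0269), in 5 of 6 lenses. This contrast and that of diploid cataract both subtract the 2N- group, whose fish had the lowest mean weight. Unigene6508 and Unigene10869 rose in both contrasts. For these genes a low level in 2N- cannot be told apart from separate changes with ploidy and with cataract. A WAS/WASL-interacting protein family 2-like transcript (Unigene5301) rose by 0.83 and gastrulation-specific protein G12 (Unigene6461) by 0.67, while a small VCP-interacting protein (Unigene3045) fell by 0.70 ± 0.13 (adjusted p = 0.03), in 6 of 6 lenses. An uncharacterised protein (Unigene10394), chosen after its values were seen, fell by 2.10, from 12.0 ± 2.32 to 2.83 ± 1.53 RPKM. Cytosolic ribosomal proteins were the only list with a camera call (median 0.06, adjusted p = 0.026; adjusted p = 0.933 with an estimated correlation). Limma called 14 unigenes, 12 that rose and 2 that fell, against 60 on RPKM as deposited, 117 with component 1 as a covariate, 178 with voom and sample quality weights and 1 with voom. The limma count was 0 with body weight as a covariate and 0 in libraries rich in connexin 43 alone, and 1956 unigenes had an unadjusted p below 0.05 in the main test. Without 2N- replicate 1, 2, 4 or 6 it was 5, 5, 25 or 8, without 3N- replicate 1, 2, 3, 4, 5 or 6 it was 74, 6, 3, 6, 3 or 3, and without 2N+ replicate 4, 3N+ replicate 3 or 3N+ replicate 7 it was 8, 22 or 8.

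The comparison of 3N+ with 2N+ asked the same in lenses with cataract, and 2 unigenes passed. The uncharacterised protein Unigene10394 fell by 1.58 ± 0.26 (log2, SE; adjusted p = 0.0438), from 8.51 ± 2.25 RPKM (SD, n = 6) to 2.10 ± 0.54 RPKM (n = 8), in 8 of 8 lenses. Unigene8661, which has no protein hit, rose by 1.72 ± 0.30 (adjusted p = 0.0438), from 7.57 ± 2.39 to 23.4 ± 8.48 RPKM, in 7 of 8 lenses. The HARBI1-like nuclease (CL18.Contig2) stood at 1.55 (adjusted p = 0.0746), and Unigene7852 and Unigene11685 at 1.21 and 0.87, none of which passed. Crystallins (51 of 55 positive, median 0.31, 0.08 on RPKM as deposited) were higher by camera at adjusted p = 3.22e-15, and lens fibre genes (median 0.26, 0.04 on RPKM as deposited) at adjusted p = 0.00149. So were ribosomal proteins (median 0.21, which turned to -0.01 on RPKM as deposited) at adjusted p = 3.84e-28 and chaperones (median 0.08, which turned to -0.13 on RPKM as deposited) at adjusted p = 0.0481. Matrix genes (median -0.27, adjusted p = 0.0012), amino acid transport (-0.70, adjusted p = 0.014), the epithelial-mesenchymal transition list (-0.37, adjusted p = 0.0333) and sterol synthesis (-0.14, adjusted p = 0.0481) were lower, beside connexin 43 means of 52.2 RPKM in 2N+ and 22.5 RPKM in 3N+. Their medians on RPKM as deposited were -0.438, -0.910, -0.557 and -0.339 in this order. Each of these 8 lists had adjusted p = 0.758 with an estimated correlation. The count of 2 was 10 on RPKM as deposited, where the median of all unigenes shifted by -0.214, 108 with voom and sample quality weights and 10 with component 1 as a covariate. It was 11 without 2N+ replicate 4, 5 without 3N+ replicate 3, 4 without 3N+ replicate 6, 1 without 2N- replicate 2, 3N- replicate 3 or 3N- replicate 6, 3 without 3N- replicate 1, 2 without 2N- replicate 6, 2N+ replicate 1 or 3N- replicate 5, and 0 in the other 16 of 26 fits that left out a fish. In limma 1565 unigenes had an unadjusted p below 0.05.

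Averaged over both cataract states, 51 unigenes differed with ploidy, 40 that rose and 11 that fell in triploids. The HARBI1-like nuclease (CL18.Contig2) rose by 1.59 ± 0.21 (log2, SE; adjusted p = 0.000455), with 5 of 6 and 8 of 8 triploid lenses above all diploid ones of the same cataract state. Ubiquitin-conjugating enzyme E2 D4 (CL1574.Contig1) rose by 0.55 (adjusted p = 0.0293), from 246 ± 12.7 to 348 ± 31.5 RPKM without (SD, n = 6) and from 238 ± 17.4 to 316 ± 34.0 RPKM with cataract (n = 8), in 6 of 6 and 8 of 8 lenses. Cytochrome P450 2K5 (Unigene10869, 1.33), S100-A14 (Unigene9480, 0.93) and the excitatory amino acid transporter 2-like transcript (Unigene7465, 0.76) rose. So did a phosphatidylinositol 3-kinase C2 (Unigene10676, 0.67), mitochondrial leucyl-tRNA synthetase (Unigene9549, 0.64), protein AF-9 (CL3435.Contig1, 0.57) and the WAS/WASL-interacting protein-like transcript (Unigene5301, 0.55). A dioxygenase of the ALKBH family (Unigene10169, 0.51), FYCO1 (Unigene10707, 0.51) and protein G12 (Unigene6461, 0.44) rose as well. A sialyltransferase (CL324.Contig2, -0.86), actin-binding LIM protein 1 (Unigene5628, -0.59) and uncoupling protein 2A (CL1232.Contig1, -0.47), a mitochondrial carrier, fell. An average does not show a difference in each cataract state, and none of the genes named in this paragraph passed with cataract alone. For cytochrome P450 2K5, Unigene7465, Unigene5301 and Unigene6461 the average was below the rise without cataract, so their rise with cataract was smaller than without. By camera, ribosomal proteins (median 0.14, adjusted p = 1.72e-18), crystallins (median 0.14, adjusted p = 0.00145) and lens fibre genes (median 0.14, adjusted p = 0.0224) were higher, and amino acid transport (median -0.71, adjusted p = 0.00832) and matrix genes (median -0.20, adjusted p = 0.0224) lower, each at adjusted p = 0.873 with an estimated correlation. On RPKM as deposited these medians were 0.041 for ribosomal proteins, 0.046 for crystallins, 0.046 for lens fibre genes, -0.807 for amino acid transport and -0.276 for matrix genes. On RPKM as deposited 61 unigenes passed, 37 higher and 24 lower. The count was 31 with relative log expression factors, 12 with body weight and 119 with component 1 as a covariate, 1057 with voom and sample quality weights, and 2 and 26 in libraries rich and poor in connexin 43. Without 1 fish it ran from 12 (without 3N- replicate 3) to 114 (without 3N- replicate 1), was 97 without 3N+ replicate 6, and lay between 14 and 31 without 2N- replicates 1, 2 or 6, 2N+ replicates 2, 3 or 6, 3N- replicates 2, 5 or 6, or 3N+ replicates 1, 2, 4, 7 or 8.

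Within groups, limma found 0 unigenes that followed body weight, with 1239 at an unadjusted p below 0.05. Voom gave 3, voom with sample quality weights 1, and limma with component 1 as a covariate 5. Leaving out 2N- replicate 6 gave 19, 2N- replicate 3 gave 5, and 3N+ replicate 1 or 5 gave 1 each.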

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

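The tests of epithelium amount, reads counted, group, blood, surface epithelium and body weight were chosen only after the results they address were seen, as was the component 1 gap of the splits, whereas the counts over other splits of the libraries were planned.

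Transcripts of the lens epithelium were high in some libraries and low in others. Connexin 43 differed 261-fold between the highest and the lowest library, and the epithelium marker with the smallest range differed 33.8-fold. The markers were connexin 43, a forkhead box E4-like unigene, SPARC, follistatin-related protein 1 and collagen XXVIII, picked after the data were seen. All but SPARC were among the leading genes of component 1, so their wide range follows in part from the choice. The range of the lens epithelium regulators list was not taken. The tables argue against a difference in reads counted, whose highest to lowest ratio was 1.22. They also argue against cataract or ploidy as the only source, since each of the 4 groups held at least 2 libraries of either kind. A partial effect of cataract or ploidy would also leave both kinds in each group, so it stays open. The 19 tested lens fibre unigenes, from a list fixed beforehand, had a median highest to lowest ratio of 1.98 (at most 5.59). Uneven amounts of lens epithelium in the samples may account for the pattern. The comparison with the fibre list cannot decide this, since the markers were picked after the data were seen. A difference between fish that is unrelated to the groups was not tested and stays open.

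Ictacalcin, leptin, hepcidin and keratin-18 were high in some lenses with cataract and led component 2, and 4 haemoglobin unigenes were among the same 25 leading genes. The tables argue against a greater or smaller amount of lens epithelium. All 4 of these transcripts exceeded every library without cataract in 3 of 7 cataract libraries poor in connexin 43 (2.4 to 7.89 RPKM) and in 5 of 7 rich ones. For leptin, hepcidin and keratin-18 they also argue against blood carried into the sample. Of the 7 cataract libraries with more haemoglobin beta than the median (32.9 RPKM) of the 8 where all 4 transcripts were high, 3 (77.7 to 302 RPKM) had each of these 3 transcripts within the range of the libraries without cataract. In 4 of the 8 haemoglobin beta was only 3.50 to 20.1 RPKM. Ictacalcin was within the range of the libraries without cataract in 1 of the 7, too few to decide by this count. It was at least 73.0 RPKM in each of the 8, so also in the 4 with low haemoglobin beta. Without cataract ictacalcin was at most 22.42 RPKM, although haemoglobin beta reached 18.25 RPKM in 2N- and 429.2 RPKM in 3N- replicate 5. These values argue against blood as the only source of ictacalcin, and a partial share from blood stays open. For the haemoglobins themselves blood was not tested and stays open. Cataract and surface epithelium carried into the sample cannot be told apart for any of the 4 transcripts. That 13 of the 14 cataract libraries lay above the highest library without cataract (-11.4) on component 2 restates the pattern. Keratin-13 had a median of 1.51 RPKM with and 1.47 RPKM without cataract (at most 8.28), but it is 1 of 6 tested keratins on the list, and which of them abound in salmon surface epithelium is not known from the tables.

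The cataract calls in diploids fell in number from 268 to 43 with body weight as a covariate. The tables argue against body weight as the source of these changes as a set, since 128 of the 268 unigenes (47.8%) had a slope on body weight within groups in the direction of their cataract change, against 49.2% of all unigenes. With the covariate the median size of the change went from 1.03 to 1.02 (log2), all 268 kept their sign, and the median SE widened from 0.228 to 0.304, which ended the calls. The weights of the diploid groups did not overlap, so a slope that differs between groups, or a step in weight, was not tested and stays open beside cataract.

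Other splits of the libraries into groups of the same sizes were counted in 100 draws, the real split included. For cataract in diploids (268 unigenes) 2 of 100 splits gave as many, the highest other being 427, and for cataract in triploids (17 unigenes) 1 of 100 did, the highest other being 6. For cataract over both ploidies (524 unigenes) 1 of 100 did, the highest other being 131. For ploidy without cataract (14 unigenes) 2 of 100 did, the highest other being 871, and for ploidy over both cataract states (51 unigenes) 2 of 100 did, the highest other being 1840. For ploidy with cataract (2 unigenes) 2 of 100 did, the highest other being 3, and for the interaction (1 unigene) 3 of 100 did, the highest other being 3. Each of these 7 shares lay under the planned threshold of 0.05, without adjustment over the 7 counts. The shares do not exclude chance for the interaction (1 unigene) or ploidy with cataract (2 unigenes). Those counts fell to 0 in 20 and 16 of the 26 fits that left out a fish. The splits with 871 and 1840 unigenes called several times the real number, which points to a structure of the samples other than the groups. They separated the libraries on component 1 by 75.2 and 54.6 between the means compared, the largest gap of the 99 splits drawn for each, against medians of 16.8 and 12.8 and gaps of 16.4 and 21.8 for the real groups. Over all 99 splits the rank correlation of the count with the gap was 0.28 and 0.15, with a median count of 0 in both.

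A single library stood apart from the others of its group in 18 of 348 groups of values (5.17%). Chance alone gives about 1 in 20 where values are normally distributed. Genes were taken as log2 of RPKM plus 0.5 and marker shares as percents. The shares were skewed, with a mean of 0.101% and a median of 0.01965% for retina markers in 2N+, so this rate need not hold for them. Each value below is the gap to the nearest library as a share of the whole range of the group, on these scales. For marker shares of reads it was 0.923 for haemoglobins in 3N- replicate 5 (0.118% of reads), 0.764 for retina markers in 2N+ replicate 2 (0.453%), 0.948 for retina markers in 3N- replicate 1 (0.265%), 0.76 for retina markers in 3N+ replicate 8 (0.0589%) and 0.537 for keratins in 3N+ replicate 6 (0.0492%), each the highest of its group. Highest of their groups were also the attractin-like Unigene3900 in 2N- replicate 4 (0.676, 7.82 RPKM), annexin A4 CL2784.Contig3 in 3N- replicate 6 (0.673, 8.71 RPKM), cytochrome c oxidase Vb Unigene9769 in 3N- replicate 1 (0.754, 17.3 RPKM) and heat shock protein 70 Unigene7837 in 3N- replicate 6 (0.691, 29.8 RPKM). Lowest were gamma-crystallin N-like CL85.Contig1 (0.608, 4121 RPKM) and gamma crystallin-like CL403.Contig1 (0.569, 6706 RPKM), both in 3N+ replicate 3, and beta-crystallin S-1-like CL1572.Contig1 in 3N- replicate 2 (0.687, 36.1 RPKM). Glycine cleavage protein H CL2430.Contig1 in 3N+ replicate 2 (0.609, 13.6 RPKM), cysteinyl-tRNA synthetase CL3670.Contig1 in 2N- replicate 2 (0.664, 9.5 RPKM) and doublecortin Unigene3251 in 2N- replicate 5 (0.662, 2.53 RPKM) were lowest too. The same held for the sialyltransferase CL324.Contig2 in 2N+ replicate 6 (0.666, 0.943 RPKM) and for uncoupling protein 2A CL1232.Contig1 in 2N- replicate 2 (0.651, 4.19 RPKM) and 2N+ replicate 1 (0.795, 6.54 RPKM).

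The interaction of cataract and ploidy passed for the beta-sarcoglycan-like Unigene5783 (-1.36, limma adjusted p = 0.0353). This call was lost in 20 of the 26 fits that left out a fish, with body weight as a covariate, on RPKM as deposited and with voom. Chance is not excluded for it. By camera the interaction passed for the crystallin list (median 0.47, 0.22 on RPKM as deposited, adjusted p = 3.58e-13), the ribosomal protein list (median 0.15, which turned to -0.10 on RPKM as deposited, adjusted p = 7.86e-08) and the sterol synthesis list (median -0.19, -0.42 on RPKM as deposited, adjusted p = 0.00938). For each of the 3 lists camera gave adjusted p = 0.827 with an estimated correlation.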

How the results depend on the processing

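The settings chosen only after the data were seen were the pseudocounts of 0.1 and 1, RPKM as deposited, voom without weights, component 1 with and without body weight, libraries rich or poor in connexin 43 and the wider crystallin description; the others were planned. A count model (edgeR or DESeq2) on the original counts was planned and not run, since the deposited values were RPKM. It was not run on the recovered reads either, on which voom was run instead. Counts are given in the order cataract in diploids, cataract in triploids, ploidy without cataract, ploidy with cataract, cataract over both ploidies, ploidy over both cataract states and interaction, with main values of 268, 17, 14, 2, 524, 51 and 1, and counts within 1.5 times the main value are left out. TMM without crystallins, a minimum of 1 CPM and a pseudocount of 1 left all 7 within that range.

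Relative log expression factors gave 31 for ploidy over both states, and upper quartile factors gave 1 for ploidy with cataract. Without a filter ploidy with cataract gave 0 and ploidy over both states 23. A pseudocount of 0.1 gave 0 for ploidy with cataract. RPKM as deposited gave 1315, 48, 60, 10 and 1432 for the first 5 counts and 0 for the interaction, beside the shift of all unigenes. Voom with quality weights gave 570, 42, 178, 108 and, for ploidy over both states, 1057, with 1 unigene for body weight within groups. Voom alone gave 10 for cataract in triploids, 1 for each pairwise ploidy contrast, 0 for the interaction and 3 for body weight. Body weight as a covariate gave 43, 0 for ploidy without cataract, 247, 12 and 0 for the interaction. Component 1 gave 780, 179, 117, 10, 1120, 119 and 2, with 5 for body weight. Component 1 with body weight gave 210 for cataract in triploids, 12 for ploidy with cataract and 0 for the interaction. Fitting the 2 groups alone gave 67 for cataract in diploids, 9 and 1 for ploidy without and with cataract, and this drops samples. Libraries rich in connexin 43, which also drops samples, gave 0 for cataract in triploids, 0 and 10 for ploidy without and with cataract, 279 and 2. Libraries poor in it gave 11, 37, 8 for ploidy with cataract, 118, 26 and 0 for the interaction. A block on the replicate number, which only shares a number (11 of 24 same-numbered pairs correlated above 0.1), gave 4 for cataract in triploids, 5 and 1 for ploidy without and with cataract, and 20 for ploidy over both states. For the other changes of setting the cause was not tested. In limma the counts at an unadjusted p below 0.05 were 1743 for cataract in triploids, 1956 and 1565 for ploidy without and with cataract, and 1203 for the interaction.

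Without each fish in turn the counts ran from 76 to 417, 5 to 43, 3 to 74, 0 to 11, 323 to 604, 12 to 114 and 0 to 1, and from 0 to 19 for body weight. The crystallin share differences kept their sign and stayed unpassed in these fits (-4.82 to -3.23 for diploid cataract, -1.64 to -0.67 for triploid cataract, -1.70 to -0.59 for ploidy without and 0.87 to 2.46 for ploidy with cataract) and with other denominators or lists. Of the 34 list calls 0 held with an estimated correlation and 39 were made with body weight. The 5 unigenes called in both ploidies were 148 at an unadjusted p of 0.01, 3 with body weight and 88 with component 1. The weight difference between 3N+ and 2N+ reversed from -0.04 (log2) to 9.79 g, neither passing. Among 110 calls of named genes 0 reversed in any of these settings, and 97 passed on RPKM as deposited, 110 with component 1, 67 with component 1 and body weight, and 39 with body weight. Of those that could be tested, 50 of 109 passed in libraries rich in connexin 43, 24 of 106 in libraries poor in it, and 13 of 48 with the 2 groups alone. The uncalled CL1968.Contig1 (0.04) reversed to -0.01 with body weight and -0.082 in libraries poor in connexin 43, and ran from -0.021 (without 3N- replicate 1; -0.011 without 2N+ replicate 5) to 0.094 without each fish in turn. The uncalled CL256.Contig3 (-0.06) reversed to 0.11 on RPKM as deposited, 0.026 with component 1 and body weight, and 0.005 in libraries rich in connexin 43. With a median of 14 reads per unigene and library, the simulated 2-fold changes called were 43.3%, so the absence of a call does not exclude a change of that size.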

Other observations

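The values in this part were chosen only after the data were seen, and no explanation was tested for them.

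Of the 25 genes that led component 2, 5 chosen here had lower group means without cataract. Among the 4 haemoglobins of the 25, haemoglobin beta had a median of 11.9 RPKM in 2N- and 48.6 RPKM in 2N+, and of 2.13 RPKM in 3N- and 33.1 RPKM in 3N+. The mean of 3N- (74.0 RPKM) rests on replicate 5 (429.2 RPKM). A leptin b unigene (Unigene7501), named for a hormone and cytokine, averaged 0.40 RPKM in 2N- and 41.0 RPKM in 2N+, and 0.36 RPKM in 3N- and 74.4 RPKM in 3N+. Hepcidin-1 (CL2143.Contig1), the iron-regulating peptide, averaged 1.14 and 24.9 RPKM in diploids without and with cataract, and 0.67 and 66.8 RPKM in triploids. Annexin A2-A (Unigene7737), a membrane-binding protein, averaged 1.56 and 14.4 RPKM in diploids and 1.06 and 21.6 RPKM in triploids. Clusterin (CL938.Contig1), a secreted chaperone, averaged 11.6 and 47.2 RPKM in diploids and 9.94 and 51.2 RPKM in triploids. S100-A1 (Unigene3929), a calcium-binding protein, averaged 16.8 and 71.5 RPKM in diploids and 20.1 and 83.7 RPKM in triploids. Apart from haemoglobin these are group means, and the cataract lenses differed widely among themselves.

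A cytosolic non-specific dipeptidase (Unigene8273) was present at 110 to 239 RPKM in 7 libraries, 2N- replicates 5 and 6, 2N+ replicates 2, 3 and 6, 3N- replicate 1 and 3N+ replicate 5, and below 1 RPKM in the other 19. Cochlin and collagens of types II and IX, known from the inner ear, cartilage and vitreous, were also higher in these 7 libraries than in the other 19, with cochlin at 7.12 to 30.8 RPKM, a collagen IX unigene at 7.06 to 27 RPKM and a collagen II unigene at 8.15 to 20.9 RPKM.

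A unigene that resembles ribosomal RNA (CL3083.Contig1) took 5.23 to 9.43% of the counted reads. By the labels 2N- replicate 4 weighed 285 g at 39 cm and 3N- replicate 4 weighed 700 g at 28.5 cm, which give condition factors of 0.48 and 3.02. The weight comparisons between groups and the contrasts with weight as a covariate used both weights as labelled. They were not repeated without these fish. The lens of 2N+ replicate 4 had adenosine deaminase (Unigene4383) at 58.9 RPKM, within the range of the diploids without cataract. No libraries were identical, and the closest pair, 2N- replicate 5 and 3N+ replicate 7, differed by a chi-square of 25.44 per degree of freedom.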
